A study of Mus musculus with 4 samples.

How the data were processed

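Mouse tracheal epithelial cells from E2f7 knockout mice and wild-type littermates, cultured to day 7 at an air-liquid interface and released with trypsin, were measured by droplet 3′ single-cell RNA sequencing, with 16000 cells loaded per library. The 4 libraries formed 2 groups, wild type (replicates A and B) and E2f7 knockout (replicates A and B), taken from the labels before the data were examined, as were the gene lists, the comparisons, the tests and the rule for named genes.

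The deposited matrices hold raw UMI counts per gene and cell barcode for 31053 genes, as whole numbers. The processing notes give Cell Ranger 3.0 and the genome mm10, and per the file headers the counts come from version 7.0.0, so the version is not settled. Whether intronic reads were counted was not given in the sources used here. The deposited feature and barcode lists are of the unit other, names in the order of the matrix. The cell table made by the authors gives library and cell class names (unit other), UMI and gene counts per cell, the percent of UMIs from mitochondrial genes, and cell cycle and pseudotime values as a score whose scale was set by the authors' method, not given in the sources used here. The deposited merged matrix came without row names and was not used; its cells were taken from the matrices of the libraries. No column of sample values was left unused (0).

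The matrices held 19593 and 14052 barcodes in wild type and 13779 and 13687 in knockout, and the cell table keeps 41958 of them. Kept cells had at least 2501 genes, at most 49997 UMIs and under 10 % mitochondrial UMIs. Of the barcodes within these bounds 840, 538, 829 and 422 were not kept, and 78.2, 81.6, 68.4 and 74.4 % of these were among the 10 % of barcodes with the highest doublet scores, against 4.02, 5.66, 5.55 and 6.66 % of kept cells (order: wild-type A, wild-type B, knockout A, knockout B). Doublet scores came from scrublet in scanpy 1.11.5; its automatic threshold called 1 barcode, so the highest 10 % of scores was used as an added alternative. Median mitochondrial shares were 5.21, 5.70, 5.23 and 5.17 %. The authors' cell classes were used: Basal stem, Basal to intermediate, Intermediate, Secretory, Tnfrsf12a+, S, G2M and Multiciliated 1, 2 and 3.

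Counts were summed over the cells of a class in a library, and a class was tested when each library held at least 50 of its cells. The S class, with 47 and 48 cells in 2 of its libraries, was left out, which leaves 9 classes and all cells together. Genes were tested with edgeR 4.0.16 (R 4.3.3; filterByExpr, TMM, quasi-likelihood test) with Benjamini-Hochberg adjustment within a comparison, and called at an adjusted p under 0.05. The difference of the knockout effect between 2 classes was tested with an interaction term and the library as a block. Shares of classes, summed levels of the S phase and of the G2 and M phase lists, and shares of cells with at least 3 UMIs of a list after thinning to 3000 UMIs were compared with exact two-sided permutation tests in scipy 1.17.1, where the smallest p for 2 against 2 is 0.333. No cell had fewer UMIs than the thinned depth. Data were simulated for this number of libraries for all cells, Basal stem, Multiciliated 1, 2 and 3 and the pairs of classes compared. The mean counts and trended dispersion of each of these were used, so genes of like level had the same dispersion. The other classes were not simulated, so the shares called do not cover them. On the simulated data, edgeR called 58 to 77 % of genes with a log2 fold change of 1 and 87 to 96 % of those with 2. There were 4 to 13 false calls per comparison. The interaction test called 43 to 68 % and 79 to 92 %. As real genes may also differ in dispersion, these shares may overstate what is called in the real data.

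The 23 gene lists covered the cell cycle (S phase, G2 and M phase, replisome, nucleotide synthesis, histones, cyclins, cell cycle inhibitors, E2F and DP family), cilia (fate regulators, centriole amplification, axonemal dynein, cilium tip, intraflagellar transport) and damage (p53 targets, DNA repair, apoptosis). Others were dissociation, interferon response, hypoxia and glycolysis, cholesterol synthesis, oxidative phosphorylation, squamous differentiation and the Notch pathway. They were tested with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation. Every list given below with a value for the estimated correlation passed the preset one. A simulated list of independent genes, raised by 1 on the log2 scale, had a camera adjusted p of 0.0356 to 0.0473 with an estimated correlation. With the preset correlation it had 3.25e-69 or less. A value above 0.05 with an estimated correlation therefore does not show that a list is unchanged. In the lists, Centrob, Dnai1, Dnai2, Tctn2, Aldoa and Hes4 matched no gene of the matrices. A gene was named when it belonged to the E2F and DP family, was among the 10 with the smallest p in its direction (called, absolute log2 fold change of at least 0.5, libraries of the 2 groups not overlapping), or among the 4 members with the smallest p of a called list; sex-linked genes were left out of the ranking. For differences between classes the genes with the smallest p were named. Positions come from GENCODE vM21 (mm10).

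Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter, at least 5 CPM in 2 libraries, the replicate letter as a block, each library left out in turn, equal numbers of cells per library, classes clustered anew without 173 cell cycle genes (Leiden, leidenalg 0.10.2, resolution 1.0 or 0.6), other depths and numbers of UMIs for the shares, and cells of high doublet score removed. Each new cluster took the name of the authors' class with the most cells in it, so the same name can cover other cells. Added after the first results were the pair Multiciliated 2 and Basal stem and the matching of cells on the authors' pseudotime. Figures were drawn with matplotlib 3.10.9.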

Results

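Single-cell RNA was measured in mouse tracheal epithelial cells grown at an air-liquid interface, a culture in which airway stem cells form basal, secretory and multiciliated cells. The cells were collected on culture day 7 from E2f7 knockout mice and wild-type littermates, with 2 libraries per group and 16000 cells loaded per library. The question was how loss of E2f7, a transcriptional repressor of the E2F family, alters the transcriptome of each cell class, multiciliated cells above all. The authors kept 12446 and 9581 wild-type cells and 10180 and 9751 knockout cells, with 162374985 to 201040854 unique molecular identifiers (UMIs) per wild-type library and 151949766 to 173936796 per knockout library. The median per cell was 14133.5 and 15202 UMIs in wild type and 13255.5 and 16032 in knockout. Values are UMI counts of all cells of a class in a library, scaled to the total of these cells (CPM) and given as mean ± SD (n = 2 libraries per group). For genes with a test this was the total of the genes tested, adjusted by TMM. For sums over a list it was the plain total, so the 2 scales differ. Log2 fold changes are knockout over wild type with their standard error (SE). The labels do not say whether the libraries of a group come from separate cultures or animals, so the p-values measure only the spread between these samples, which may be technical.

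The transcript of E2f7 (ENSMUSG00000020185, mm10 chromosome 10, 110745439 to 110787384, plus strand) was detected in every library. Over all cells it stood at 25.1 and 17.3 CPM in the wild-type libraries and at 77.3 and 71.6 CPM in the knockout libraries (log2 fold change 1.81, SE 0.18, adjusted p = 0.105). In Multiciliated 1 it rose from 246 ± 9.02 to 483 ± 3.34 CPM (log2 fold change 0.97, SE 0.10, adjusted p = 0.0473). In Multiciliated 2 it rose from 83.2 ± 7.66 to 303 ± 10.1 CPM (log2 fold change 1.86, SE 0.12, adjusted p = 0.000249). Without knockout replicate A these adjusted p-values were 0.517 and 0.0611, and without knockout replicate B 0.228 and 0.0643. Multiciliated 3 held 8.78 and 4.11 CPM of E2f7 in wild type and 14.1 and 6.96 CPM in knockout. In the G2M class the log2 fold change was -0.20 (adjusted p = 0.936). The libraries count the 3′ end of each transcript and the part of the gene that the allele removes was not given in the sources used here, so these levels check nothing about the deletion.

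The DNA replication program was higher in knockout Multiciliated 2, the class with the highest level of Ccna1 and of Opcml. Hells, a helicase-like chromatin remodeller, rose from 7.82 ± 0.636 to 127 ± 3.04 CPM (log2 fold change 4.0, SE 0.14, adjusted p = 3.53e-05; mm10 chromosome 19, 38930915 to 38971051). Lig1, the ligase that joins replicated DNA fragments, rose from 24.8 ± 0.0112 to 235 ± 11.3 CPM (log2 fold change 3.25, SE 0.12, adjusted p = 3.53e-05; chromosome 7, 13277283 to 13311433). Pcna, the sliding clamp of DNA polymerases, rose from 4.35 ± 0.487 to 54.9 ± 7.27 CPM (log2 fold change 3.68, SE 0.19, adjusted p = 0.000136). Hist1h1c, a linker histone gene, fell by 2.43 on the log2 scale, from 193 ± 7.93 to 35.8 ± 0.0641 CPM (SE 0.11, adjusted p = 7.08e-05; chromosome 13, 23738808 to 23740367). Of 14039 genes tested, 541 rose and 488 fell.

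Among the gene lists in Multiciliated 2, the S phase genes had 32 of 42 members called up, 37 when adjusted over the list alone. Their median log2 fold change was 1.62 with all 42 above 0 (adjusted p = 0.328 with an estimated correlation). The pre-replication complex and replisome genes had 34 of 50 called up, among them Mcm7 (2.88) and Pola1 (2.79). Adjusted over the list alone 40 were called up and 1 down, and the median was 1.22 (adjusted p = 0.328 with an estimated correlation). DNA repair genes had a median of 1.05 and 16 of 28 called up (21 adjusted over the list alone), such as the mismatch repair genes Msh2 (2.63) and Msh6 (2.44). Nucleotide synthesis genes had a median of 0.79 and 11 of 23 called up (13 adjusted over the list alone), such as Dut (1.53) and Rrm1 (1.03). Both lists gave an adjusted p = 0.328 with an estimated correlation. Activator members of the E2F family rose, with E2f1 at 3.12 (SE 0.38, adjusted p = 0.00504) and E2f3 at 1.69 (SE 0.19, adjusted p = 0.0037). The closest relative of E2f7, E2f8, rose by 3.43 (SE 0.23, adjusted p = 0.000349). That family had 6 of 10 members called up, 7 adjusted over the list alone, and a median of 1.23 (adjusted p = 0.328 with an estimated correlation). The cell cycle lists share some members, in every class, so their counts of calls are not independent of each other.

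Histone genes of Multiciliated 2 had 4 of 15 members called down and 2 up (6 down and 2 up adjusted over the list alone), with a median of -0.46 (adjusted p = 0.328 with an estimated correlation). Hist1h2bc fell by 3.69, Hist2h3c2 by 3.51 and Hist1h4i by 2.26 on the log2 scale, whereas Hist1h1b rose by 1.72. Capture of histone transcripts by 3′ sequencing was not tested. The changes of histone genes, here and in the other classes, may thus not be changes of total histone RNA. The 3 cilium lists were lower. Of the cilium tip, radial spoke and central apparatus genes 12 of 41 fell (24 adjusted over the list alone; median -0.41), as did 10 of 33 axonemal dynein and assembly genes (19 adjusted over the list alone; median -0.39). Of 44 intraflagellar transport and transition zone genes, 7 fell, such as Wdr19 (-0.92), and 1 rose. Adjusted over the list alone these were 16 down and 1 up, with a median of -0.25. Each of the 3 gave an adjusted p = 0.328 with an estimated correlation. The p53 targets had 7 of 29 members called up and 2 down (10 up and 2 down adjusted over the list alone; median 0.37). Mdm2, which targets p53 for degradation, rose by 0.87 and the death receptor gene Fas had -1.25. Cell cycle inhibitors had 2 of 14 called up, Cdkn1a (0.70) and Rbl1 (0.89), and 1 down, Cdkn1c (-1.47), with a median of 0.32 (3 up and 1 down adjusted over the list alone). The adjusted p = 0.328 with an estimated correlation for p53 targets and inhibitors. Centriole amplification genes had 5 of 30 members called up, such as Cep152 (0.72), and 1 down, Cetn4 (-0.75), with a median of 0.28 (8 up and 1 down adjusted over the list alone). Dissociation and immediate early genes had none of 25 called and a median of -0.25 (4 down adjusted over the list alone). Both had an adjusted p = 0.457 with an estimated correlation. G2 and M phase genes had a median of 0.23 and 4 of 53 called up, 6 up and 3 down adjusted over the list alone (adjusted p = 0.676 with an estimated correlation). Without wild-type replicate B the median was 0.0926 for G2 and M phase, -0.83 for histones, 0.17 for centriole amplification and -0.16 for dissociation genes, and without wild-type replicate A 0.47, -0.27, 0.35 and -0.44. Without knockout replicate A 18 genes were called in Multiciliated 2 and without knockout replicate B 14, against 1584 without wild-type replicate A. With no filter on low counts 277 were called. In the class clustered anew without cell cycle genes, which holds partly other cells, 1906 were called (817 up, 1089 down).

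Multiciliated 1, the class with the highest level of Mcidas, Ccno and Deup1, genes of early multiciliated cells, showed a smaller set of changes led by the same program. Mcm4, a subunit of the replicative helicase, rose from 9.94 ± 1.65 to 63.8 ± 1.71 CPM (log2 fold change 2.70, SE 0.15, adjusted p = 0.016; mm10 chromosome 16, 15623897 to 15637400). Hells rose by 2.15 (SE 0.12, adjusted p = 0.016), and Uhrf1, which maintains DNA methylation at replication, by 2.25 (SE 0.13, adjusted p = 0.016). E2f1 rose by 2.51 (SE 0.20, adjusted p = 0.032), from 2.49 ± 0.0729 to 14.3 ± 0.874 CPM. Hist1h1c (-1.36, SE 0.14, adjusted p = 0.0473) and Hist1h2bc (-1.65, SE 0.19, adjusted p = 0.0493) were the 2 genes that fell, and 39 rose, of 14309 tested. In the same libraries 203 genes were called by DESeq2, 158 with no filter on low counts and 84 in classes clustered anew without cell cycle genes.

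In Multiciliated 1 the S phase list had 13 of 43 members called up (31 adjusted over the list alone; median 0.93) and the replisome list 9 of 50 (36 adjusted over the list alone; median 0.84). Nucleotide synthesis had none of 24 (7 adjusted over the list alone; median 0.35). All 3 had an adjusted p = 0.211 with an estimated correlation. DNA repair genes had 5 of 30 called up, among them Rad51 (1.40) and Brca2 (1.16), with 13 adjusted over the list alone and a median of 0.66 (adjusted p = 0.216 with an estimated correlation). The E2F family had 3 of 10 called up, E2f1, E2f7 and E2f8 (1.54), 4 up and 1 down adjusted over the list alone, with a median of 0.38 (adjusted p = 0.290 with an estimated correlation). Histone genes had a median of -0.25 with 1 of 17 called up, Hist1h1a (2.33), and 2 down (2 up and 4 down adjusted over the list alone). Centriole amplification genes had a median of 0.22, 28 of 30 above 0 and none called (2 adjusted over the list alone). Both lists had an adjusted p = 0.523 with an estimated correlation. Cilium genes were not lower in this class. The median was 0.15 for axonemal dynein (31 of 33 above 0; adjusted p = 0.568 with an estimated correlation) and 0.20 for the cilium tip (36 of 41; adjusted p = 0.546 with an estimated correlation). None was called over all genes or adjusted over the list alone. Intraflagellar transport genes had 1 of 44 called up, Ift27 (1.19), 2 adjusted over the list alone, and a median of 0.12 (adjusted p = 0.543 with an estimated correlation). Other lists past the preset correlation were G2 and M phase (median 0.15; adjusted p = 0.651 with an estimated correlation), dissociation (-0.27; -0.42 without wild-type replicate A), hypoxia and glycolysis (-0.14), squamous differentiation (-0.46; 7 genes) and cell cycle inhibitors (0.11; 0.19 without wild-type replicate B). None of their genes was called over all genes, and the last 4 each had an adjusted p = 0.523 with an estimated correlation. Without wild-type replicate B the median was 0.0173 for axonemal dynein, 0.0744 for the cilium tip, 0.0417 for intraflagellar transport, 0.12 for centriole amplification, -0.0423 for G2 and M phase and -0.93 for squamous differentiation. Without wild-type replicate A the first 5 of these were 0.35, 0.40, 0.24, 0.37 and 0.46, and histones had 0.0881 (-0.59 without knockout replicate B). Every call in Multiciliated 1 ended when knockout replicate A or knockout replicate B was left out (0 genes each), whereas 1330 genes were called without wild-type replicate A (662 up, 668 down) and 432 without wild-type replicate B (302 up, 130 down).

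In Multiciliated 3, the class with the highest levels of Calml4 and Ccdc33, the cilium program and sterol synthesis were lower in the knockout. Dnah10, an axonemal dynein heavy chain, fell from 190 ± 22.0 to 76.2 ± 5.65 CPM (log2 fold change -1.32, SE 0.11, adjusted p = 0.00787; mm10 chromosome 5, 124725085 to 124834308). Sntn, a protein of the cilium tip, fell from 450 ± 17.5 to 249 ± 5.40 CPM (-0.85, SE 0.08, adjusted p = 0.00991). Hmgcs1, a cholesterol synthesis enzyme, fell from 320 ± 7.17 to 159 ± 11.1 CPM (-1.01, SE 0.09, adjusted p = 0.00859; chromosome 13, 119690379 to 119708260). Sftpc, a surfactant protein gene, had the smallest p (-2.72, SE 0.09, adjusted p = 0.00111; chromosome 14, 70520949 to 70524081), at 163 ± 11.3 CPM in wild type and 24.7 ± 0.601 in knockout. Gmnc, a regulator of multiciliated cell fate, rose from 26.8 ± 1.76 to 69.7 ± 0.297 CPM (1.38, SE 0.08, adjusted p = 0.00555; chromosome 16, 26913553 to 26991652). Of 16373 genes tested 321 rose, with other examples in Cidea (1.38), Ntf3 (1.32) and Pigr (1.10), and 734 fell, with other examples in Iyd (-2.89), Jam3 (-2.04), Myl4 (-1.64) and Odf3b (-1.25).

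Of the lists in Multiciliated 3, the cilium tip, radial spoke and central apparatus genes had 21 of 42 members called down (35 adjusted over the list alone; median -0.43), such as Iqca (-0.91) and Tekt4 (-0.83). Cholesterol synthesis had 13 of 22 called down (19 adjusted over the list alone; median -0.58), such as Msmo1 (-0.98) and Hmgcr (-0.75). Each of these had an adjusted p = 0.148 with an estimated correlation. Axonemal dynein and assembly genes had 16 of 33 called down (25 adjusted over the list alone; median -0.41; adjusted p = 0.228 with an estimated correlation). Intraflagellar transport and transition zone genes had 14 of 44 called down, among them Ahi1 (-0.83), B9d1 (-0.72) and Ift27 (-0.66), 34 adjusted over the list alone, with a median of -0.34 (adjusted p = 0.276 with an estimated correlation). Dissociation and immediate early genes had 2 of 25 called up, Jun (0.66) and Klf2 (0.66), 3 adjusted over the list alone and a median of 0.15. The p53 targets had 2 of 30 called up and 2 down, such as Ccng1 (0.65) and Bbc3 (-0.67), 8 up and 2 down adjusted over the list alone and a median of 0.22. For both the adjusted p = 0.276 with an estimated correlation. The S phase list had 2 members called up, Hells (1.04) one of them, and 1 down, Rfc2 (-0.61), 7 up and 1 down adjusted over the list alone, with a median of 0.33 (0.19 without knockout replicate A; adjusted p = 0.945 with an estimated correlation). E2f1 rose by 1.11 (adjusted p = 0.0183). The summed level of 54 G2 and M phase genes was 0.697 times that of wild type (4854 ± 364 and 3381 ± 1.39 CPM; exact permutation p = 0.333, two-sided, the smallest that 2 against 2 libraries allow). Tubb4b, a tubulin gene, carried this sum (4100 and 3812 CPM in wild type, 2381 and 2579 CPM in knockout; log2 fold change -0.67, adjusted p = 0.0249). The list itself had a median of -0.0326 with 3 of 52 called down. Summed over the list, markers of secretory cells moved up beside the cilium genes, from 20079 ± 1266 to 32609 ± 3499 CPM. Reg3g had the largest change (means of 5861 CPM in wild type and 12028 in knockout). Cyp2f2 (4799 and 7236) and Cbr2 (3897 and 5952) came next. Scgb1a1 (53.9 and 49.3), Scgb3a1 (461 and 337), Scgb3a2 (298 and 142), Bpifb1 and Chil4 had lower means in the knockout, and the other markers higher ones. Leaving out knockout replicate A left 211 genes called in Multiciliated 3 and leaving out knockout replicate B 44, against 1055 with all libraries, 700 without wild-type replicate A and 1578 without wild-type replicate B. No filter gave 2267 genes, and classes clustered anew without cell cycle genes 1774.

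**Figure D1:**
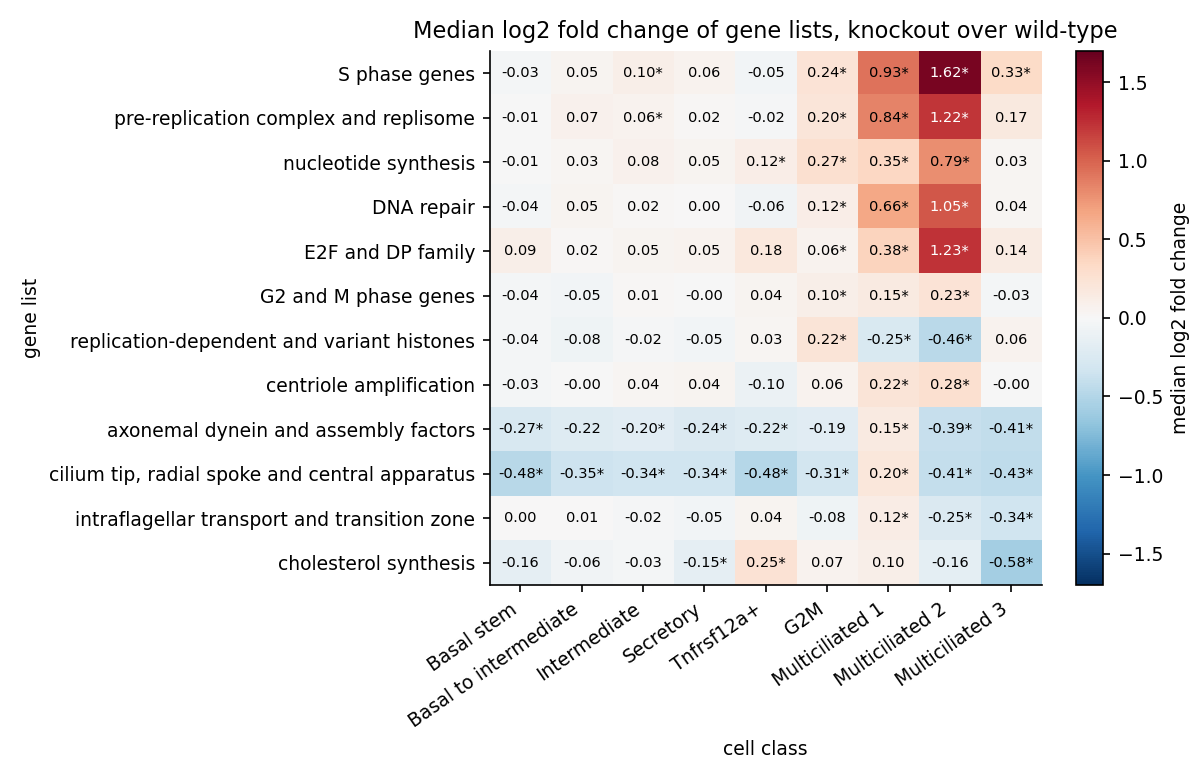
Median log2 fold change (knockout over wild type) of some of the gene lists in each tested cell class, by colour and printed value. An asterisk marks an adjusted p under 0.05 by camera with the preset correlation, which no list reached with an estimated one. The S phase list reached 1.62 in Multiciliated 2 and 0.93 in Multiciliated 1, and the cilium tip list -0.43 in Multiciliated 3.

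Whether the knockout effect differed between classes was tested directly. Mcm4 rose more in Multiciliated 1 than in Basal stem cells by 2.77 (SE 0.23, adjusted p = 0.00225) and than in Secretory cells by 2.79 (SE 0.16, adjusted p = 0.00229). Siva1, an apoptosis regulator, rose more by 1.7 (SE 0.11) and 1.68 (SE 0.10). Ift27, an intraflagellar transport subunit, rose in Multiciliated 1 and fell in Multiciliated 3, a difference of 1.88 (SE 0.10, adjusted p = 0.00284), the smallest p of that pair. Krt14, a basal keratin, had a lower effect in Multiciliated 1 than in Basal stem cells (-1.30, SE 0.15, adjusted p = 0.00773). Its level was only 8.08 CPM in Multiciliated 1, against 299 CPM in Basal stem cells. Effects differed for 91 genes between Multiciliated 1 and Basal stem (77 higher, 14 lower in Multiciliated 1) and for 77 between Multiciliated 1 and Secretory (67 and 10). They differed for 1095 between Multiciliated 1 and Multiciliated 3 (736 and 359) and for 268 between Multiciliated 3 and Basal stem (168 and 100). Multiciliated 2 and Basal stem, a pair added after the first results, differed for 382 genes (291 and 91), with Pcna higher by 3.85 (SE 0.21, adjusted p = 6.33e-06) and Hist1h2bc lower by -3.65 (SE 0.23, adjusted p = 1.47e-05). In the order given, these counts were 20, 64, 144, 98 and 108 without knockout replicate A, 66, 27, 204, 45 and 59 without knockout replicate B. Between Multiciliated 1 and Basal stem the split was 28 higher and 38 lower without knockout replicate B and 335 and 295 without wild-type replicate A, where Multiciliated 1 and Secretory had 643 and 517. They were 630, 1160, 2086, 863 and 1337 without wild-type replicate A and 627, 500, 1402, 757 and 1028 without wild-type replicate B, and 541, 549, 2177, 1033 and 939 with no filter.

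Cells with S phase transcripts were counted after thinning each cell to 3000 UMIs, as the share of cells with at least 3 UMIs of the 43 S phase genes. In Multiciliated 1 the share was 60.4 ± 1.52 % in wild type and 91.6 ± 1.40 % in knockout (n = 2 libraries each), and in Multiciliated 2 it was 41.2 ± 1.67 % and 94.8 ± 1.37 %. In Multiciliated 3 it was 17.8 ± 1.24 % and 18.8 ± 2.43 %. Secretory cells had the lowest shares, 11.9 ± 0.650 % and 11.5 ± 0.280 %. Those of Multiciliated 3 were near those of Basal stem (18.1 and 17.9 % in wild type, 17.9 and 14.5 % in knockout) and Tnfrsf12a+ cells (19.3 and 18.8 %, 16.1 and 17.2 %). Before thinning the median depth was 13507 to 16446 UMIs in Secretory cells, against 21549 to 27450 in Multiciliated 1 and 25215 to 33319 in Multiciliated 2. Without thinning the shares were 98.9 % and 99.6 % in Multiciliated 1 and 100 % in both groups in Multiciliated 2, so the unthinned measure is saturated. Summed over the S phase list, the level was 1139 ± 84.7 and 2288 ± 2.31 CPM in Multiciliated 1 (2.01-fold) and 765 ± 30.2 and 2299 ± 91.0 CPM in Multiciliated 2 (3.0-fold). In Multiciliated 3 it was 497 ± 19.1 and 522 ± 41.0 CPM (1.05-fold). Both differences in share and both in level of Multiciliated 1 and Multiciliated 2 were larger than the spread between libraries, each with an exact permutation p = 0.333 (two-sided, the smallest possible).

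**Figure D2:**
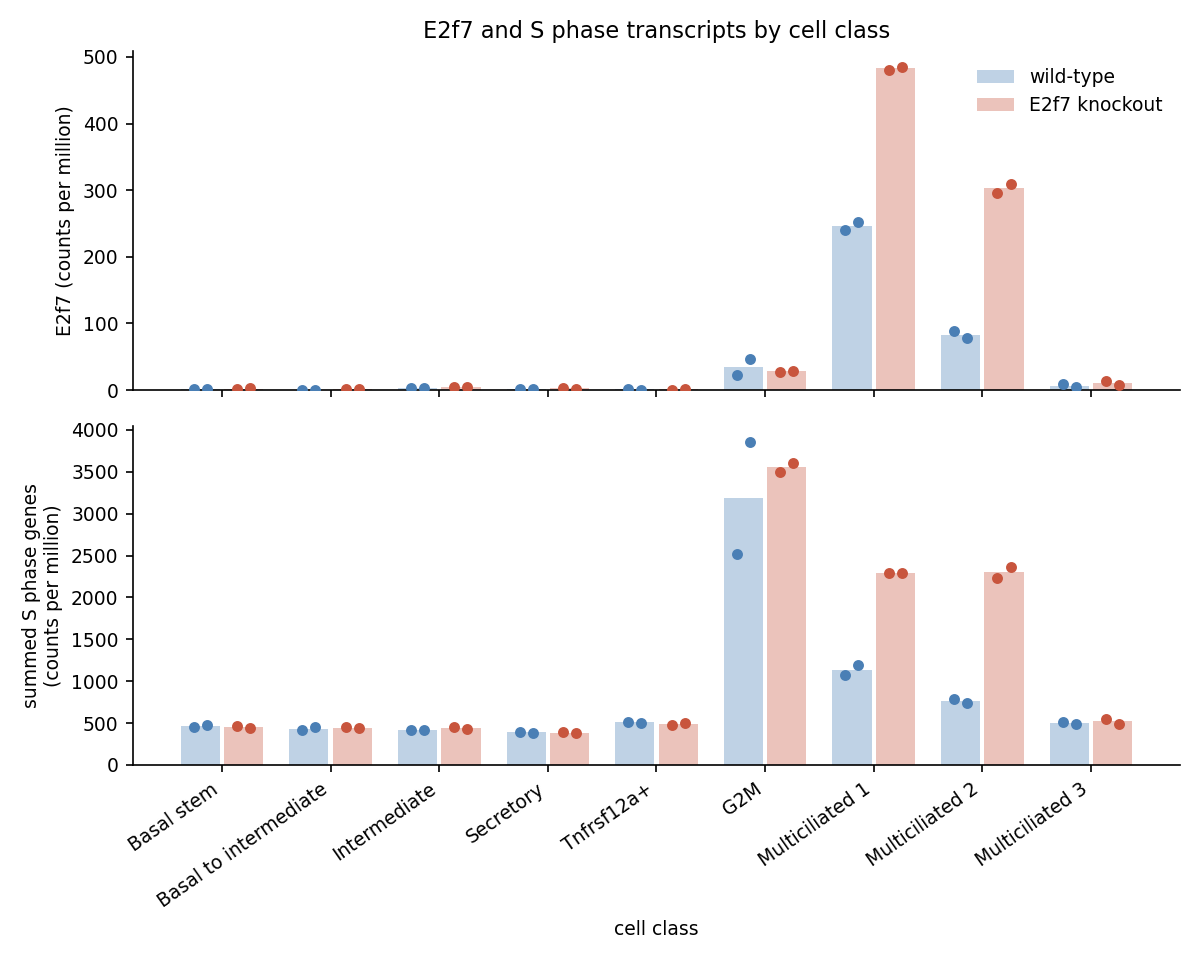
Summed level of the S phase genes (CPM) in each library of each cell class, wild type and knockout. The wild-type libraries of Multiciliated 2 sit at 786 and 744 CPM and its knockout libraries at 2234 and 2363 CPM.

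Multiciliated 1 and Multiciliated 2 made up a larger share of the knockout libraries. Multiciliated 1 made up 4.40 ± 1.21 % of wild-type and 6.95 ± 0.356 % of knockout cells, and Multiciliated 2 made up 1.89 ± 0.603 % and 3.50 ± 0.198 %. The libraries did not overlap in either class (exact permutation p = 0.333, two-sided, the smallest possible and the share of splits where chance gives no overlap). Multiciliated 3 overlapped, at 13.8 and 14.8 % in wild type and 14.2 and 18.5 % in knockout. All 3 multiciliated classes together held 20.6 ± 1.08 % and 26.8 ± 2.55 %. No class was called by edgeR on the cell counts. Multiciliated 2 had a log2 fold change of 0.89 (adjusted p = 0.438) and was the 1 class at an unadjusted p under 0.05, Multiciliated 1 had 0.66 (adjusted p = 0.608) and the others an adjusted p = 0.902. The sizes of the multiciliated classes depend on the authors' clustering, whose input genes are not known. In classes clustered anew without the cell cycle genes, the library shares of Multiciliated 2 overlapped, at 2.47 and 1.37 % in wild type and 3.16 and 2.17 % in knockout. Those of Multiciliated 1 did not, at 6.11 and 3.87 % and at 9.27 and 8.89 %. The new Multiciliated 2 held 571 cells of the authors' class and 392 of their Multiciliated 3. A new cluster named Multiciliated 1 took 553 cells of the authors' Multiciliated 2. These shares therefore compare other mixes of cells under the same names. Secretory cells made up 22.7 ± 1.36 % and 20.3 ± 1.04 %, and cells of the G2M class 2.84 and 0.918 % of the wild-type libraries and 1.26 and 1.497 % of the knockout libraries.

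**Figure D3:**
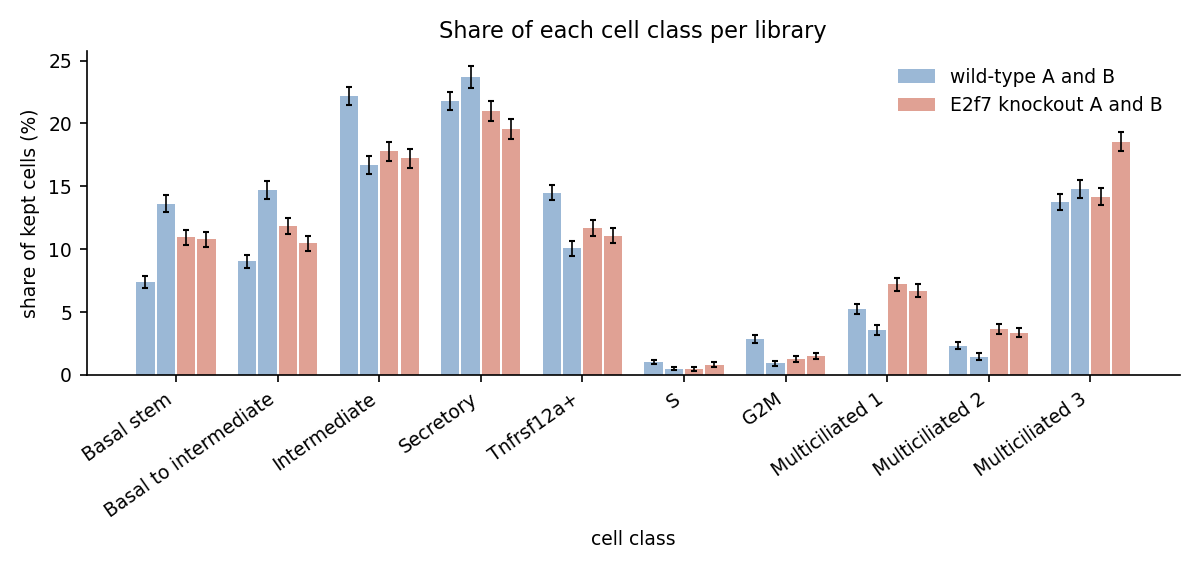
Share of cells (%) in each class, for each of the 2 wild-type and 2 knockout libraries. Multiciliated 1 lies at 5.25 and 3.55 % in wild type and at 7.20 and 6.70 % in knockout.

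Cyp2b10, a cytochrome P450 gene (mm10 chromosome 7, 25897620 to 25926624), was the single gene called in Basal stem cells, where it rose from 41.5 ± 5.55 to 184 ± 27.2 CPM (log2 fold change 2.14, SE 0.14, adjusted p = 0.00398). It was also the single gene called in Intermediate cells, where it rose from 63.6 ± 0.523 to 208 ± 13.3 CPM (1.71, SE 0.09, adjusted p = 0.0121). Its effect was lower in Multiciliated 1 than in Basal stem cells by -1.52 (SE 0.15, adjusted p = 0.00405) and in Multiciliated 3 by -1.93 (SE 0.14, adjusted p = 0.00107). Both calls ended without knockout replicate A and without knockout replicate B (0 genes in each class). DESeq2 called 5 genes in Basal stem and 18 in Intermediate cells, and 147 and 258 were called with no filter on low counts; without wild-type replicate A the counts were 34 and 6, and without wild-type replicate B 68 and 9.

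No gene was called by edgeR in the Basal to intermediate, Secretory, Tnfrsf12a+ and G2M classes, where 354, 648, 760 and 734 genes had an unadjusted p under 0.05 and DESeq2 called 5, 43, 22 and 6. With no filter on low counts 14, 14, 152 and 132 were called. Interferon response genes were lower in knockout Tnfrsf12a+ cells, with a median of -0.86 and all 25 below 0. None was called over all genes and 17 adjusted over the list alone (adjusted p = 0.759 with an estimated correlation). Bst2, an antiviral tetherin, stood at 75.5 ± 5.43 CPM in wild type and 41.7 ± 4.78 in knockout. The same list was higher in Basal stem (0.20; adjusted p = 0.978 with an estimated correlation) and Basal to intermediate (0.35; adjusted p = 0.831 with an estimated correlation). It was also higher in Intermediate (0.22; adjusted p = 0.442 with an estimated correlation) and Secretory cells (0.13; adjusted p = 0.590 with an estimated correlation). Without wild-type replicate B the interferon median was 0.0813 in Basal stem, 0.15 in Basal to intermediate, 0.0960 in Intermediate, 0.00599 in Secretory and -1.12 in Tnfrsf12a+ cells. Without wild-type replicate A it was 0.52, 0.50, 0.41, 0.28 and -0.49. Cilium tip genes had a median of -0.48 in Basal stem, -0.35 in Basal to intermediate, -0.34 in Intermediate, -0.34 in Secretory and -0.48 in Tnfrsf12a+ cells, with the same values with an estimated correlation as the interferon list of each class. Without wild-type replicate B these medians were -0.78, -0.52, -0.54, -0.48 and -0.69, and over all libraries left out the values nearest 0 were -0.27, -0.21, -0.15, -0.19 and -0.28. Dissociation and immediate early genes had -0.18 in Basal stem, -0.23 in Basal to intermediate, -0.23 in Intermediate, -0.14 in Secretory and -0.32 in G2M cells. Without wild-type replicate A these were -0.15 in Basal to intermediate and -0.12 in G2M cells, and without knockout replicate B -0.0935 in Secretory cells. Axonemal dynein genes had -0.27 in Basal stem, -0.24 in Secretory, -0.22 in Tnfrsf12a+ and -0.20 in Intermediate cells (adjusted p = 0.546 with an estimated correlation for the last). Without wild-type replicate A they had -0.0994 in Basal stem, -0.0662 in Intermediate and -0.000294 in Tnfrsf12a+ cells, and without knockout replicate A -0.15 in Secretory cells. Without wild-type replicate B they had -0.35 in Intermediate and -0.36 in Tnfrsf12a+ cells. Cilium transcripts were scarce in these classes, with Sntn at 1.88 to 2.11 CPM against 348 CPM in Multiciliated 3. Of the genes 10 or more times higher in Multiciliated 3, 80.9 % had a mean log2 fold change below 0 over the 5 classes. Cholesterol synthesis was lower in Secretory (-0.15) and higher in Tnfrsf12a+ cells (0.25), oxidative phosphorylation was higher in Basal stem (0.05), Secretory (0.05) and Tnfrsf12a+ cells (0.11). Notch pathway genes were lower in Intermediate (-0.10) and Secretory cells (-0.13). All lists above without a value had the adjusted p with an estimated correlation of the interferon list of their class. Further lists past the preset correlation in Intermediate cells were S phase (0.10), the replisome (0.06) and multiciliated cell fate regulators (0.10). In Tnfrsf12a+ cells nucleotide synthesis (0.12) also passed it. None of these passed with an estimated correlation. Cholesterol synthesis had -0.0393 in Secretory cells without knockout replicate A and 0.0668 in Tnfrsf12a+ cells without knockout replicate B, and the Notch pathway -0.0249 in Intermediate cells without wild-type replicate B. Without wild-type replicate A oxidative phosphorylation had 0.11 in Basal stem and Secretory cells and the Notch pathway -0.22 in Secretory cells. In the G2M class 12 lists passed the preset correlation, among them S phase (0.24), nucleotide synthesis (0.27) and p53 targets (0.29), with an adjusted p = 0.552 with an estimated correlation for each. Without wild-type replicate A S phase and nucleotide synthesis had -0.15 and -0.0227 there, and without knockout replicate B p53 targets had 0.13. Apoptosis (-0.06 to 0.34) and the cyclins and cyclin-dependent kinases (-0.07 to 0.24) passed in no class. The counts over all genes in the 4 classes were 2, 2, 0 and 13 without knockout replicate A, 2, 1, 0 and 3 without knockout replicate B. They were 57, 115, 224 and 4 without wild-type replicate A and 189, 174, 348 and 153 without wild-type replicate B.

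Over all cells together no gene was called by edgeR, with 2071 of 19152 at an unadjusted p under 0.05, a smallest adjusted p = 0.0520 and 606 genes called by DESeq2 (120 by edgeR with no filter). Lig1 (1.52, SE 0.11, adjusted p = 0.0749), Dtl, a receptor of the ubiquitin ligase that removes the licensing factor Cdt1 (1.61, SE 0.15, adjusted p = 0.0977), and Gmnc (0.81, SE 0.08, adjusted p = 0.0977) were among the genes nearest to a call. The S phase list had a median of 0.48 with 25 genes up and 1 down adjusted over the list alone, and centriole amplification 0.46 with 22 up and 1 down. Multiciliated cell fate regulators had a median of 0.22 with 10 up adjusted over the list alone, replisome genes 0.31 with 18 and DNA repair genes 0.34 with 7. These 5 lists had an adjusted p = 0.454 with an estimated correlation. Without wild-type replicate B replisome and DNA repair genes each had 0.19, and without wild-type replicate A 0.57. Without wild-type replicate A 975 genes were called over all cells and without wild-type replicate B 405, and none without either knockout replicate. Summed markers of early multiciliated cells stood at 886 and 722 CPM in the wild-type and 1294 and 1240 CPM in the knockout libraries, and those of tuft cells at 143 and 136 and at 120 and 72.5 CPM. The early multiciliated list holds E2f7 itself, at 25.1 and 17.3 CPM in wild type and 77.3 and 71.6 CPM in knockout over all cells. The tuft list was highest in Secretory cells (197 CPM, with Trpm5 at 0.0461), so its sum does not count tuft cells.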

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

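Some of the tests here were chosen only after the result was seen. They were the pair Multiciliated 2 and Basal stem, the matching on pseudotime, the transcripts of other cell types and the genes 10 or more times higher in Multiciliated 3.

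These results stand out because the knockout effect differed between cell classes in the same libraries. It differed for 91 genes between Multiciliated 1 and Basal stem, 268 between Multiciliated 3 and Basal stem, 1095 between Multiciliated 1 and Multiciliated 3, 77 between Multiciliated 1 and Secretory and 382 between Multiciliated 2 and Basal stem. Leaving out knockout replicate A gave 20, 98, 144, 64 and 108 genes and knockout replicate B 66, 45, 204, 27 and 59. With DESeq2 size factors, the 258 genes between Multiciliated 3 and Basal stem were split into 129 higher and 129 lower, against 168 and 100. The lists below passed the preset correlation, and none did with an estimated correlation, where their adjusted p ran from 0.128 to 0.959.

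Between Multiciliated 1 and Basal stem the median difference of log2 fold change was 0.88 for S phase genes, 0.86 for the replisome, 0.36 for nucleotide synthesis, 0.66 for DNA repair, 0.27 for G2 and M phase, 0.31 for centriole amplification, 0.45 for axonemal dynein, 0.73 for the cilium tip, 0.19 for intraflagellar transport and 0.24 for cholesterol synthesis. Against Secretory cells, the same lists differed in Multiciliated 1 by 0.80, 0.83, 0.20, 0.63, 0.20, 0.21, 0.44, 0.56, 0.21 and 0.23, the dissociation list by -0.17 and squamous differentiation by -0.46. Against Multiciliated 3, they differed by 0.72, 0.76, 0.33, 0.63, 0.20, 0.28, 0.62, 0.68, 0.51 and 0.70, and histones by -0.45, p53 targets by -0.21, the dissociation list by -0.49 and oxidative phosphorylation by 0.14.

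Multiciliated 3 differed from Basal stem by 0.29 for S phase genes, -0.18 for axonemal dynein, -0.33 for intraflagellar transport, -0.57 for cholesterol synthesis, 0.19 for p53 targets, 0.45 for the dissociation list, -0.28 for the interferon response and -0.10 for oxidative phosphorylation. The effect on the cilium tip list was not called different from that in Basal stem for Multiciliated 3 (0.08, adjusted p = 0.869) or Multiciliated 2 (0.14, adjusted p = 0.867). The cilium transcripts were scarce in Basal stem and Secretory cells (Sntn 2.10 and 2.05 CPM, against 348 in Multiciliated 3) and may be free RNA there. Of the genes 10 or more times higher in Multiciliated 3, 80.9 % had a mean log2 fold change below 0 in the 5 classes without cilia. Multiciliated markers summed over all kept cells overlapped between groups, however (3988 and 3930 CPM in wild type, 3968 and 4423 CPM in knockout). A smaller source of free RNA in the knockout is thus not shown, and the origin of these transcripts was not settled. Comparing the cilium lists with these classes therefore does not show whether the effect is specific to multiciliated cells. Multiciliated 2 differed from Basal stem by 1.62 for S phase genes, 1.20 for the replisome, 0.66 for nucleotide synthesis, 0.97 for DNA repair, 0.95 for the E2F and DP family, 0.30 for G2 and M phase, 0.22 for centriole amplification, 0.38 for p53 targets, -0.39 for histones and -0.27 for intraflagellar transport.

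The rise of S phase genes in Multiciliated 1 and Multiciliated 2 was set against doublets with cycling cells, free RNA and a shift of stage. Doublets would need a share of 39.4 and 46.6 % of RNA from the S class, with its Krt5 and Krt14, and the observed change of these was at most -0.00915 of that rise. The S phase level in Basal stem and Secretory cells changed by at most -0.000964 of the rise in Multiciliated 2, which argues against free RNA. With cells of Multiciliated 2 matched on the authors' pseudotime, the median log2 fold change was 0.922 of the unmatched one (1.49 against 1.62), although that pseudotime may itself use cell cycle genes. An effect of E2f7 loss and another difference between the animals both stay open, and neither was tested apart from the other.

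The fall of cilium genes in Multiciliated 3 was set against a shift of stage and against RNA of other cell types. Matching on pseudotime left 0.957 of the median log2 fold change in the cells with a pseudotime (-0.31 against -0.32), a part of the class with a smaller effect than the whole (-0.39). Dilution would need 23.8 % of foreign RNA, and the secretory marker list rose by 0.538 of what that share would bring, just past the bound of 0.5 set before the test, as did 7 of its 16 genes, 5 of them with more than dilution gives (Lypd2 5.27, Cyp2a5 3.96, Cyp2f2 1.38, Gsto1 1.03 and Cbr2 1.02). After the result was seen this was nevertheless read as counting against dilution as the whole cause. The reason was that Scgb1a1, Scgb3a1, Scgb3a2 and Bpifa1 gave only -0.0132, -0.0428, -0.107 and 0.0316 of the needed rise. Transcripts chosen in each of 5 other classes, at 300 or more CPM and 10 or more times the wild-type level in Multiciliated 3, had a median of at most 0.209. These sets overlapped, with Tgfb2 in those of Basal stem, Basal to intermediate, Intermediate and Secretory cells. The Intermediate set held only 3 transcripts, Scgb3a2 among them. An effect of E2f7 loss, a partial dilution and other differences between the animals stay open.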

How the results depend on the processing

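The removal of high doublet scores, the matching on pseudotime and the pair Multiciliated 2 and Basal stem were chosen only after the result was seen. With 2 libraries per group, counts of called genes rest on each library. Of 139 single-gene results, 92 were no longer called without knockout replicate A, 103 without knockout replicate B, 20 with no filter and 3 with DESeq2, and none changed with DESeq2 size factors. With the replicate block 12 were no longer called, in classes clustered without cell cycle genes 9 and with equal cells per library 9. Directions turned for E2f7 alone, in classes where it was not called. Keeping cells with at least 1000 genes and at most 10 % mitochondrial UMIs removed no cell. For the values below that differ from those with all libraries and the first settings, the cause was not tested, except that leaving out a library leaves 3 samples.

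DESeq2 called 606 genes over all cells, 5 in Basal stem, 5 in Basal to intermediate, 18 in Intermediate, 43 in Secretory, 22 in Tnfrsf12a+, 6 in G2M and 203 in Multiciliated 1 cells. With no filter, 120 genes were called over all cells, 147 in Basal stem, 14 in Basal to intermediate, 258 in Intermediate, 14 in Secretory, 152 in Tnfrsf12a+, 132 in G2M, 158 in Multiciliated 1, 277 in Multiciliated 2 and 2267 in Multiciliated 3 cells. Without a filter, effects differed for 541 genes between Multiciliated 1 and Basal stem, 1033 between Multiciliated 3 and Basal stem, 2177 between Multiciliated 1 and 3, 549 between Multiciliated 1 and Secretory and 939 between Multiciliated 2 and Basal stem. At least 5 CPM in 2 libraries gave 6 genes over all cells and 1 in Secretory cells. Equal cells per library gave 1 gene over all cells, as did removing high doublet scores (1). Classes clustered without cell cycle genes gave 1 gene in Basal to intermediate, 1 in Tnfrsf12a+, 84 in Multiciliated 1, 1906 in Multiciliated 2 and 1774 in Multiciliated 3. These classes hold partly other cells than the authors' classes of the same name. The estimated correlation left 0 lists called in each of the 9 classes and over all cells. Without thinning, the difference in the share of cells with S phase transcripts over all cells was -0.567 points, and with at least 2 UMIs that in Multiciliated 3 was -0.957 points.

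With the replicate letter as a block (replicate block), 2 genes were called in Basal stem, 1 in Basal to intermediate, 8 in Secretory, 1 in Tnfrsf12a+, 22 in G2M, 165 in Multiciliated 1 (102 up, 63 down), 478 in Multiciliated 2 and 2372 in Multiciliated 3 cells. The labels do not say that the letters pair the libraries, and the deviations of libraries with the same letter correlated across genes from -0.159 in Multiciliated 2 to 0.132 in Multiciliated 3.

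Leaving out 1 library at a time, the called genes ran from 0 to 975 over all cells, 0 to 68 in Basal stem, 2 to 189 in Basal to intermediate, 0 to 9 in Intermediate, 1 to 174 in Secretory, 0 to 348 in Tnfrsf12a+, 3 to 153 in G2M, 0 to 1330 in Multiciliated 1, 14 to 1584 in Multiciliated 2 and 44 to 1578 in Multiciliated 3. Genes with a different effect ran from 20 to 630 (Multiciliated 1 and Basal stem), 45 to 863 (Multiciliated 3 and Basal stem), 144 to 2086 (Multiciliated 1 and 3), 27 to 1160 (Multiciliated 1 and Secretory) and 59 to 1337 (Multiciliated 2 and Basal stem). The lists called ran from 3 to 7 in Basal stem, 3 to 6 in Basal to intermediate, 5 to 12 in Intermediate, 4 to 13 in Secretory, 6 to 14 in G2M and 7 to 12 in Multiciliated 3.

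Directions turned in that way for some lists, as medians of log2 fold change: G2 and M phase ran from -0.0834 to 0.89 over all cells and -0.0423 to 0.46 in Multiciliated 1, where histones ran from -0.59 to 0.0881. Axonemal dynein ran from -0.36 to -0.000294 in Tnfrsf12a+ cells, where the median stayed below 0 and only the direction of the list test turned. In the G2M class S phase genes ran from -0.15 to 0.57, G2 and M phase from -0.00836 to 0.25, the replisome from -0.12 to 0.49, the E2F family from -0.0450 to 0.26, DNA repair from -0.15 to 0.36, nucleotide synthesis from -0.0227 to 0.53, the cilium tip from -0.57 to 0.0396 and the interferon response from -0.61 to 0.30. E2f7 ran from -0.0147 to 1.18 in Basal stem, -0.19 to 1.46 in Tnfrsf12a+ and -0.73 to 0.29 in G2M cells.

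Differences in the share of a class, in points, ran from -2.76 to 3.49 for Basal stem, -3.55 to 2.13 for Basal to intermediate, -4.65 to 0.820 for Intermediate, -3.15 to 1.29 for Tnfrsf12a+, -0.364 to 0.150 for S, -1.46 to 0.459 for G2M and -0.117 to 4.27 for Multiciliated 3. Summed levels (log2) of S phase genes ran from -0.0285 to 0.0171 in Secretory and -0.0107 to 0.15 in Multiciliated 3, and of G2 and M phase genes from -0.0131 to 0.16 in Multiciliated 2. Shares of cells with S phase transcripts differed by -0.798 to 0.121 points in Secretory and -0.779 to 2.66 in Multiciliated 3, and with G2 and M phase transcripts by -1.31 to 0.113 in Multiciliated 3.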

Other observations

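All tests in this part on genes specific to multiciliated cells and on genes shared by 5 classes were chosen only after the result was seen, and for chromosome 8 the bound of the test was also changed after it was seen.

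Genes specific to multiciliated cells (at least 20 times the level of the other classes and at least 50 CPM) were mostly lower in knockout Multiciliated 2 and Multiciliated 3 and mostly higher in Multiciliated 1. In Multiciliated 3, 326 of 339 were lower, 177 fell and 0 rose by edgeR, with a median log2 fold change of -0.46. In Multiciliated 2, 120 of 339 fell and 1 rose (median -0.44), and in Multiciliated 1, 255 of 338 were higher (median 0.17) with none called, among 1449 genes at an unadjusted p under 0.05 in that class and 203 called by DESeq2. The counts of calls rest on all 4 libraries: Multiciliated 2 held 18 and 14 called genes of any kind without knockout replicate A or B, and Multiciliated 3 211 and 44.

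The authors' own S phase score had a median of 0.0240 in wild-type and 0.0534 in knockout Multiciliated 1, and of 0.0133 and 0.0413 in Multiciliated 2. Summed over all cells of a library, markers of ionocytes stood at 59.9 and 72.4 CPM in wild type and 40.6 and 50.04 in knockout. Immune markers stood at 184 and 397 CPM and at 244 and 543 CPM, so they differed more within than between groups. These sums do not count such cells. The immune list was highest in Secretory cells (1088 CPM, of which Lyz2 gave 1057), and the ionocyte list in Multiciliated 3 (99.6 CPM, with Foxi1 at 0.00734). Xist stood at 347 and 187 CPM in wild type and 374 and 334 in knockout, and the Y-linked Uty at 37.3 and 60.1 and at 39.2 and 37.9, so every library held cells of both sexes, and wild-type replicate B had the lowest Xist and the highest Uty.

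In each of Basal stem, Basal to intermediate, Intermediate, Secretory and Tnfrsf12a+ cells, 104 genes were lower and 89 higher in both knockout libraries than in both wild-type libraries, of 12380 tested, and only Cyp2b10 was called by edgeR in any of these classes. The other 2 splits of the 4 libraries gave more such genes, 373 for replicates A against replicates B and 231 for the remaining split, so the count of 193 is no sign of an effect of the knockout. Tle6 (-2.76) had the largest mean log2 fold change of the lower genes, and Cyp2b10 (1.63) and Cd74 (1.36) of the higher genes.

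Free RNA of multiciliated cells may be behind part of the shared lower genes. Of the genes 10 or more times higher in Multiciliated 3, 80.9 % had a mean log2 fold change below 0, against 49.7 % of all genes. Such genes made up 32.7 % of the shared lower genes, against 3.17 % of those tested and 0 of the 89 higher genes. That was under the bound of 50 % written for this measure, so by it free RNA was not the source of most shared lower genes. Summed over all kept cells, multiciliated markers overlapped between the groups (3988 and 3930 CPM in wild type, 3968 and 4423 CPM in knockout). A smaller source of such RNA in the knockout is therefore not shown, and free RNA stays open. Genes within 20 Mb of E2f7 were 1.17 times as frequent among the shared genes as among those tested (3 of 193, Fisher exact p = 0.744). As the count of shared genes is no sign of a knockout effect, this cannot decide on DNA carried with the allele. A stretch of chromosome 8 that differs between the animals cannot be told apart from other causes, since the chromosome held 24 of the 158 shared genes with a known chromosome left after removing the lower multiciliated ones, 2.76 times its share (Fisher exact, adjusted p = 0.000121 over 22 chromosomes). The densest 20 Mb window there held 10 genes against a median of 9 in random draws (permutation p = 0.310), which by itself is no sign of clustering. Under the bound first written (p over 0.2) that counted against a stretch, and the bound was changed after the result was seen because a stretch longer than the window leaves no dense window. Chance and differences between single libraries stay open for these genes, and the tests on chromosomes were not run on the other splits.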
